A study of Homo sapiens with 4 samples.

How the data were processed

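RNA from 4 human cell samples was measured on 4 one-colour Agilent expression arrays. The samples were HK-1 wild type, HK-1 with an MCL-1 knockout, C666-1 wild type and C666-1 with an MCL-1 knockout, with 1 array each. Per the labels' protocols, total RNA was extracted with TRIzol, and 50 ng was labelled with Cy3 using Agilent's One-Color Low Input Quick Amp kit, in which cDNA synthesis is primed from poly(A) tails. The knockouts were made with CRISPR-Cas9, per the series' design text, and both knockout samples carry guide number 2 in their labels. All 4 arrays were labelled as slide 1, so slide was no batch within the set. Sample groups came from the labels alone. Nothing in the labels says how many cultures or clones stand behind a sample, so a spread between these arrays may be technical.

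The authors scanned the arrays and extracted spot brightness with Agilent Feature Extraction 11.5.1.1, per the file headers and the submitters' processing notes. Per the file headers, the processed intensity of each spot was background-subtracted with spatial detrending and multiplicatively detrended within the array, small values were replaced by a surrogate, and no step put the arrays on a common scale. The deposited files also hold the raw median intensity of each spot and of its local background, and flags for outlier spots, outlier backgrounds, saturation and signal well above background. The authors' deposited value table holds log2 values whose scaling was found by setting them against the scanner files. Within each cell line, its differences between knockout and wild type matched those of the log2 processed signal at r = 1.00 across probes, with constant offsets of 0.03 in HK-1 and 0.0018 in C666-1 after 75th percentile scaling. Its column medians were 0.14 for HK-1 wild type, -0.25 for HK-1 knockout, 0.16 for C666-1 wild type and -0.06 for C666-1 knockout. Its values were centred per probe within a cell line, as the comparison between lines showed (r = 0.31). The baseline of that centring stayed unknown, so the table was used as an alternative for the knockout differences and gave none for the difference between lines.

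Each array held 62976 spots, of which 2075 were control spots and were left out of the gene values. Spots flagged as outliers, spots with an outlier background and spots inside a blemish were also left out, 1041 on the HK-1 wild-type array and 142, 100 and 77 on the HK-1 knockout, C666-1 wild-type and C666-1 knockout arrays. The blemish rule was added after maps of the arrays had been seen. It removed a spot when at least 30% of its neighbours, within 3 rows and 2 columns and at least 8 in number, were over 2 log2 units brighter than the median of the other arrays. Shares of 30, 40 and 50% were tried and marked 777, 425 and 174 spots of the HK-1 wild-type array. The 30% rule marked 34, 22 and 5 spots on the other arrays. No spot was saturated.

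The log2 of the processed intensity, minus its 75th percentile on each array, was averaged over the spots of a probe (300 probes had 10 spots). Probes were named through their RefSeq accession with the gene table of GRCh38.p14, which held 24782 of 50096 accessions. The other probes stayed unnamed, since the files used here hold no column of gene names. The arrays' grid was built on hg19, per the file headers, so no coordinates are given. The host of a small nucleolar RNA was the shortest gene, itself no small RNA gene, whose span in that table holds it, without regard to strand. Of 58201 probes, 31104 had a gene name and 27097 did not. These covered 22439 genes, and 94 probes are not reported here. A gene took the value of its probe with the highest mean signal over the 4 arrays, and 22095 genes remained. Within a line, a gene was measured when it was well above background on both arrays. A gene well above background on only 1 array of a line has a bound: the bright value over the higher of the dim array's lowest well-above-background signal and the gene's own dim value, written as "at least N-fold". Each bound was computed after 75th percentile scaling and again relative to the median gene, and the smaller of the 2 folds is given.

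With 1 array per group there is no replicate check and no p-value within a line. A gene was called higher or lower there at 2-fold or more. Each of 32 gene lists was described by its median and by that median's percentile among 10000 random lists of the same size. The random lists were matched on mean signal over the 4 arrays, and a list stood apart below 2.5 or above 97.5. Over both lines, the log2 values of genes well above background on at least 2 arrays were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend), with genotype and cell line as terms and 1 residual degree of freedom. Calls used Benjamini-Hochberg adjusted p under 0.05. The lists were tested on that fit with fry, and with camera at an estimated correlation as an alternative. The prior degrees of freedom of the fit were infinite, so every gene was judged by the spread expected at its signal and not by its own, and a gene that moved in 1 line alone could be called. The lists, the size and list rules, the tests and the rule for the genes named here were fixed before the data were examined. That rule took MCL1, the 12 largest increases and decreases per line, the 5 largest bounds per direction, up to 10 genes per direction 2-fold in both lines, the 10 largest changes called in the fit, up to 6 opposite genes, 2 to 4 members per list and the 8 largest differences between the wild-type lines per direction. It passed over genes whose symbol is a LOC, XLOC, lnc-, LINC, ENST or clone name, so each ranking given here is among the genes it covers. Some genes that the rule takes are not reported here.

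The median gene was 0.35 log2 units higher on the HK-1 knockout array than on the HK-1 wild-type array after 75th percentile scaling, and 0.12 higher in C666-1. Changes are therefore given as relative log2 changes, which are the knockout minus the wild type minus that shift. The alternatives were normexp background correction with an offset of 50, quantile normalization, scaling to the median of probes above background, the authors' table, no filter on dim probes, a filter requiring all 4 arrays, the mean of all probes of a gene, a 1.5-fold rule, a fit without the cell line, eBayes without trend and camera. Normexp used the median spot signal, because the files hold no mean spot signal. A further 5 alternatives were chosen after seeing the data: keeping blemished spots, using spot flags only, robust moderation, changes relative to the median gene, and a fit with each value not well above background raised to the array's lowest well-above-background signal.

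On simulated data with the real genes, noise of 0.2 log2 units per array and 100 changed genes per size, the 2-fold rule recovered 97% of 1.5 log2 changes in HK-1 (13041 genes, 4 false calls) and 95% in C666-1 (13914 genes, 7 false calls), and the fit over both lines recovered 100% (15093 genes, 11 false calls). All 3 recovered 100% of 3 log2 changes. Of 78 unshifted lists, 3 stood apart. The shifted list had an adjusted p of 0.649 in limma's fry, so that test had little power here, and 1 unshifted list was called. The simulated noise was independent between genes and below the SD between probes of a gene, 0.49 in HK-1 and 0.39 in C666-1. The false calls and the unshifted lists apart therefore do not give the error rates of the real arrays.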

Results

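The data describe how the transcriptome differed between MCL-1 knockout and wild-type cells of 2 nasopharyngeal carcinoma lines. HK-1 is a squamous line that lacks Epstein-Barr virus, and C666-1 is an undifferentiated line that carries it. MCL-1 is an anti-apoptotic protein of the BCL-2 family. The 4 groups, wild type and knockout of each line, had 1 array each. The 75th percentile of processed signal was 161 on the HK-1 wild-type array, 254 on the HK-1 knockout array, 324 on the C666-1 wild-type array and 394 on the C666-1 knockout array, and 45.8%, 47.5%, 47.9% and 50.1% of gene spots were well above background. The number of arrays limits the precision, and no change has a replicate check. The error that the arrays show was 0.20 log2 units per change from the scanner software, 0.09 in HK-1 and 0.08 in C666-1 between replicate spots, and 0.49 in HK-1 and 0.39 in C666-1 (SD) between different probes of a gene. Control RNAs spiked into the samples (spike-ins, 8 of them well above background) were also compared between knockout and wild type. After 75th percentile scaling their median log2 change was -0.56 (SD 0.06) in HK-1 and -0.48 (SD 0.07) in C666-1. Higher and lower are therefore meant here relative to the other genes of the arrays, and not relative to the spike-ins. Across 11999 genes, which are not independent replicates, the knockout and wild-type arrays correlated at 0.953 in HK-1 and 0.985 in C666-1.

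MCL1 mRNA, the transcript of the targeted gene, was detected on all 4 arrays. Its log2 signal over the 75th percentile was 3.22 in HK-1 wild type and 3.34 in the HK-1 array labelled knockout, and 3.95 and 3.51 in the corresponding C666-1 arrays. The relative log2 change was -0.23 in HK-1 and -0.56 in C666-1, against errors between probes of 0.49 and 0.39. In HK-1 the sign turned with the scale, from 0.12 after 75th percentile scaling to -0.23 relative to the median gene, and it was 0.23 relative to the median gene with no filter on dim probes. CRISPR-Cas9 edits can abolish a protein without lowering its mRNA, and where the probe lies relative to the edit is unknown, so MCL1 mRNA does not check the labels. Each direction given here therefore rests on the labels, and "knockout" stands for the array labelled knockout.

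The BCL-2 family, whose members restrain or trigger mitochondrial apoptosis, had different values in the 2 lines, a difference that was not tested. Transcripts of the pro-survival relative BCL2L1 (BCL-XL) had a relative log2 change of 0.91 in the HK-1 knockout and of -1.23 in the C666-1 knockout. BCL2, another pro-survival member, had -0.03 and -0.65, BCL2L2 had -0.43 and 0.02, and BCL2A1 had 0.08 and -0.14. A second BCL2 probe gave 0.46 in C666-1 after 75th percentile scaling, against -0.53 for the one used. The median of the 5 measured pro-survival genes, MCL1 included, was -0.03 in HK-1 (percentile 46.9) and -0.56 in C666-1 (percentile 0.83, apart from matched lists). In C666-1 that median was the value of MCL1 itself, with BCL2L1 and BCL2 below it and BCL2L2 and BCL2A1 above it. That C666-1 call was lost with normexp background correction (percentile 20.9), with no filter on dim probes (5.67) and with the mean of all probes (10.3).

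Among the BH3-only and effector genes, which promote apoptosis, PMAIP1 (NOXA), whose protein binds MCL-1, had the lowest C666-1 change among those measured, -1.43, with -0.45 in HK-1. The effector BAX had 0.88 in HK-1 and 0.25 in C666-1, BCL2L11 (BIM) had 0.68 and -0.08, BAD had 0.63 and -0.33, and BID had 0.62 and -0.12. Other probes disagreed after 75th percentile scaling: 2 of BCL2L11 gave 0.34 and 0.05 in HK-1 and -1.50 and -0.70 in C666-1, against 1.03 and 0.04, and 1 of BAX gave -0.58 in C666-1, against 0.37. BIK had -0.47 and 0.68, BNIP3L had 0.06 and 0.65, BNIP3 had 0.53 and 0.42, BAK1 had 0.27 and -0.50, HRK had -0.80 and -0.18, and BOK had 0.09 and -0.53. BMF, not well above background in HK-1 wild type, had -0.68 in C666-1. The median was 0.27 over 11 genes in HK-1 (percentile 68.3) and -0.15 over 12 genes in C666-1 (percentile 6.16). No BCL-2 family gene was called by limma over both lines. BNIP3, BOK and BCL2A1 each lay beside a bright spot on 1 of the arrays, meaning within 6 rows and 1 column of a spot over 16-fold brighter than on the line's other array.

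**Figure D1:**
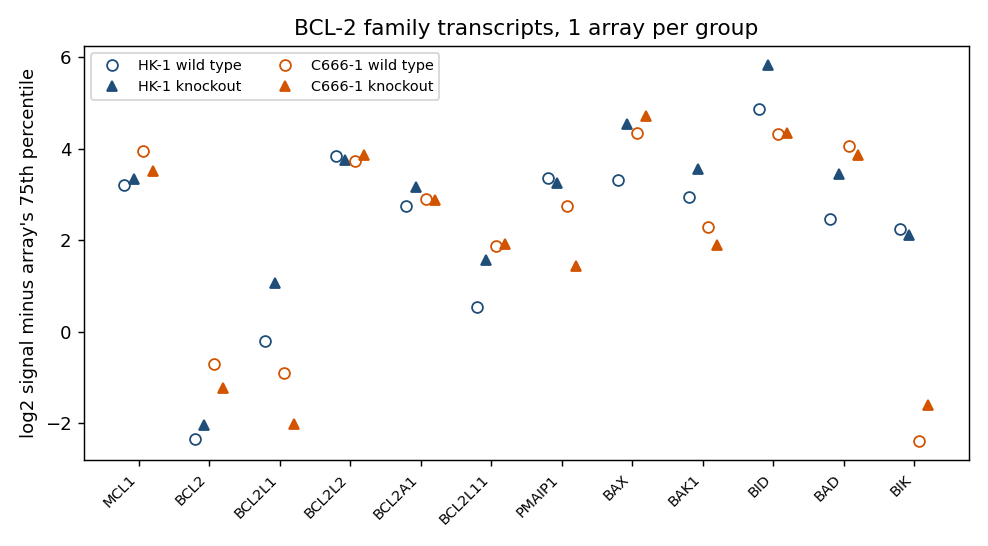
Log2 signal over the array's 75th percentile (axis in log2 units) of 12 BCL-2 family genes on the wild-type and knockout arrays of HK-1 and C666-1, with 1 array per point and no replicates. MCL1 lay at 3.22 and 3.34 in HK-1 and at 3.95 and 3.51 in C666-1, and BCL2L1 moved up in HK-1 and down in C666-1.

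In HK-1, the knockout array showed more transcripts of DNA replication and of the respiratory chain and fewer of the basal squamous programme. The HK-1 wild-type array correlated at 0.798 and 0.782 with the C666-1 arrays, against 0.837 and 0.820 for the HK-1 knockout array. In turn, the C666-1 knockout array correlated less with both HK-1 arrays than the C666-1 wild-type array did. These values therefore do not say which array departed. On the HK-1 wild-type array, 777 spots lay in blemishes. The median HK-1 change climbed from -0.22 in the dimmest of 5 signal classes to 0.69 in the brightest, and the percentiles given here are against genes of the same signal. All 30 genes of G1/S transition and DNA replication lay above the line's median gene (list median 0.87, percentile 100), led by the S-phase cyclin CCNE2 (2.11), the flap endonuclease FEN1 (1.85), the histone mRNA-binding protein SLBP (1.66) and the ribonucleotide reductase subunit RRM2 (1.47). Of 32 oxidative phosphorylation genes, 29 lay above it (median 0.67, percentile 99.97), among them SDHB (1.56), ATP5F1B (1.27) and SDHD (1.08). Of 21 basal keratin and squamous lineage genes, 19 lay below it (median -0.83, percentile 0.19), including NGFR (-1.87), KRT16 (-1.56) and KRT15 (-1.56). Of 21 cholesterol synthesis genes, 18 lay below it (median -0.68, percentile 0), with the sterol-sensing transcription factor SREBF2 at -2.05 and SQLE at -1.33, while PMVK stood at 1.30.

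A further 5 lists stood apart in HK-1. The unfolded protein and integrated stress response list had a median of -0.64 (18 of 23 genes below the median gene, percentile 0), with CHAC1 at -1.65, although DNAJB9 had 1.12. Immediate-early and MAPK feedback genes had a median of -0.53 (19 of 24 below, percentile 0.40), with EGR2 at -3.16, EGR1 at -2.33 and FOS at -1.94, while ETV5 stood at 1.76. Antigen presentation genes had a median of -0.43 (14 of 18 below, percentile 1.18), with HLA-DMA at -1.26 and the immunoproteasome subunit PSMB8 at 0.93. Extracellular proteases and inhibitors had a median of -0.82 (13 of 19 below, percentile 2.42), with TIMP3 at -2.46, MMP14 at -2.18, TIMP2 at -2.15 and the urokinase gene PLAU at -2.10. The p53 target list had a median of 0.68 (14 of 23 above, percentile 99.9), with TIGAR at 1.92, AEN at 1.74 and TRIAP1 at 1.32 against GDF15 at -2.46.

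Of the single genes covered by the naming rule and measured on both HK-1 arrays, SPRR3, a cornified envelope precursor, had the highest relative log2 change (3.33). It was followed by S100A8 (2.62), a calcium-binding protein of squamous epithelium and myeloid cells, the ribosome assembly factor PNO1 (2.48), and the heat shock genes HSPH1 (2.33) and HSPA6 (2.17). THYN1 (2.19), KCNE5 (2.18), FAM98A (2.13), DRC8 (2.12), CCNE2 (2.11), the cell cycle phosphatase CDC25A (2.05) and the splicing factor SF3B4 (2.03) made up the rest of the 12 highest. S100A9, the partner of S100A8, was not well above background in the wild type and was at least 3.53-fold higher in the knockout. The sulfotransferase SULT1C3 was at least 15.5-fold higher there, FAM222A at least 7.6-fold, LETR1 at least 4.88-fold and AKAP7 at least 4.75-fold.

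Among genes covered by the naming rule and measured on both HK-1 arrays, the lowest values were those of C19orf12 (-6.95), CASC15 (-6.10), CD86 (-5.77), NALF1-IT1 (-5.74), CCNT2-AS1 (-5.71) and FIBCD1 (-5.06). Next among the genes covered came the interferon-induced IFITM1 (-4.39), CCDC3 (-4.20), the transcription factor MLXIPL (-4.03), the growth factor BMP7 (-3.99), PPP6R1 (-3.95) and VILL (-3.89). NCR1 was at least 60.8-fold lower, GPR179 at least 48.3-fold, PROX2 at least 39.7-fold, LRRC2 at least 26.6-fold and SLC38A4 at least 24.8-fold, none of them well above background in the knockout. Second probes of C19orf12 and FIBCD1 gave 0.31 and 0.63 after 75th percentile scaling, so those values rest on 1 probe each. NCR1, PROX2, SLC38A4, FIBCD1, CD86 and DRC8 lay beside at least 1 bright spot on the HK-1 wild-type array, as did FEN1 and CHAC1.

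Of 13041 genes measured in HK-1, 2449 were at least 2-fold higher and 942 at least 2-fold lower after 75th percentile scaling, which is 72.2% higher. Relative to the median gene the counts were 862 and 1733, or 33.2% higher, and the share was 52.4% with quantile normalization, 52.2% with median scaling, 88.8% with normexp and 74.6% in the authors' deposited table. The direction of the whole set thus depended on the scaling, while the lists were set against matched genes of the same arrays. After 75th percentile scaling a further 387 genes had a bound in the higher direction (83 at least 2-fold) and 255 in the lower (217 at least 2-fold). The p53 call was lost when blemished spots were kept (percentile 96.0), with spot flags only (96.3) and with normexp (48.3). The protease call was lost under 5 of the 7 alternatives that could move it (percentiles of 3.14 to 11.6), and the immediate-early call with the mean of all probes (3.75).

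In C666-1, the knockout array showed more transcripts of interferon response and antigen presentation and fewer of the immediate-early genes, of the joint list of NRF2 targets and metallothioneins, and of cholesterol synthesis. Of 22 interferon-stimulated genes, 21 lay above the line's median gene (median 0.55, percentile 100), with the antiviral GTPase MX1 at 1.80, OASL at 1.44 and IFIT2 at 0.87. Of 19 antigen presentation genes, 15 lay above it (median 0.29, percentile 100), with HLA-DRB1 at 1.05 and HLA-DMA at 0.55. Of 24 immediate-early and MAPK feedback genes, 19 lay below it (median -0.71, percentile 0), with FOSB at -3.38, EGR2 at -2.79, ETV5 at -2.68, FOS at -2.01 and EGR1 at -0.76. Of 20 cholesterol synthesis genes, 18 lay below it (median -0.52, percentile 0), with SQLE at -0.45 and SREBF2 at -0.36.

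NRF2 targets and metallothioneins had a C666-1 median of -0.65 (8 of 11 below, percentile 0), with the zinc-binding MT1X at -3.39, MT1E at -2.61 and MT2A at -2.58. The unfolded protein and integrated stress response list had a median of -0.25 (15 of 22 below, percentile 0.08), with the endoplasmic reticulum chaperone PDIA4 at -4.06 and ATF3 at -1.60, and the list's call was lost with no filter on dim probes (percentile 3.18). The other ATF3 probes gave -2.50 to -0.20 after 75th percentile scaling, against -1.48 for the one used. Glycolysis and hypoxia response genes had a median of 0.15 (16 of 26 above, percentile 99.8), with PFKP at 1.42, NDRG1 at 0.53 and VEGFA at -0.73.

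The gene with the highest C666-1 change among those covered by the naming rule and measured on both arrays was DPPA2 (5.99), a chromatin-binding protein of early embryos and germ cells. DPPA4, its partner, was at least 14.1-fold higher and not well above background in the wild type. The adhesion genes NRCAM (4.29) and ADGRL3 (3.55) and the growth factor HGF (3.48) followed, then STON1-GTF2A1L (3.03), DSCR8 (2.97), the ubiquitin ligase MID1 (2.95), the hemidesmosome collagen COL17A1 (2.81), LRRN3 (2.61), NTN4 (2.5), GASK1B (2.48) and RADX (2.46). HOATZ was at least 59.6-fold higher, the angiotensin receptor AGTR1 at least 19.4-fold, LINGO2 at least 15.4-fold and PCDH9 at least 10.1-fold. A second MID1 probe gave 2.02 after 75th percentile scaling, against 3.07 for the one used.

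Among genes covered by the naming rule and measured on both C666-1 arrays, the lowest values were those of SMPX (-5.12), the semaphorin SEMA5A (-4.44), the neuropeptide NTS (-4.11), PDIA4 (-4.06), the ribosomal RNA gene RNA28SN5 (-3.97), the transcription factors USF1 (-3.74), NR4A2 (-3.43) and FOSB (-3.38), UGT2B10 (-3.43), MT1X (-3.39) and TMEM95 (-3.06). NR3C1, the glucocorticoid receptor, was at least 50.8-fold lower on its brightest probe, which was not well above background in the knockout. Neither of its other 2 probes was well above background on both C666-1 arrays. ZPLD1 was at least 20.8-fold lower, the adrenergic receptor ADRA2A at least 17.2-fold, DSC1 at least 16.7-fold and CLEC4GP1 at least 15.6-fold. SREBF2 lay beside 2 bright spots on the C666-1 wild-type array, and COL17A1 lay beside 1 on the knockout array.

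Of 13914 genes measured in C666-1, 355 were at least 2-fold higher and 391 at least 2-fold lower after 75th percentile scaling (47.6% higher). Relative to the median gene the counts were 255 and 525 (32.7% higher). Bounds on the 75th percentile scale gave 455 further genes higher (72 at least 2-fold) and 218 lower (113 at least 2-fold).

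The other lists did not stand apart at the settings used here. In HK-1 and C666-1 in turn, the medians were 0.19 (percentile 85.3) and -0.01 (41.6) for caspases, death receptors and IAPs, where cytochrome c (CYCS) had 2.03 and -0.04 and 1 of the other CYCS probes gave 0.51 in HK-1 after 75th percentile scaling, against 2.38 for the one used. They were 0.43 (83.9) and 0.02 (60.4) for G2/M and mitosis, with AURKB at 1.21 and -0.31 and TOP2A at 1.06 and 0.11, and 0.24 (57.8) and 0.04 (53.2) for DNA damage repair, with EXO1, which lay beside a bright spot on the C666-1 wild-type array, at 1.71 and 0.15. Mitochondrial dynamics and fatty acid oxidation had 0.23 (55.0) and -0.02 (35.4), autophagy 0.02 (18.0) and -0.02 (27.6), MCL-1 protein turnover and binding partners 0.40 (87.6) and 0.01 (48.8), and housekeeping genes 0.30 (41.2) and -0.09 (35.5). NF-kB and inflammatory mediators had 0.07 (90.7) and 0.14 (82.1), with RELB at 1.25 and 0.52. EMT and mesenchymal genes had -0.64 (6.05) and -0.08 (33.2), with the matricellular CCN2 at -2.20 and 1.03, and epithelial adhesion had -0.32 (24.3) and 0.11 (79.2), with EPCAM at 0.06 and 1.35. Keratinocyte terminal differentiation had -0.69 (13.4) and 0.33 (96.2), simple and ciliated epithelium -0.50 (26.7) and -0.15 (18.0), and WNT and Notch pathways -0.24 (29.1) and -0.0046 (51.9), with WNT5A at -2.98 and 0.33. Lists apart in 1 line had in the other 0.04 (69.3) for p53 targets, -0.09 (4.80) for G1/S, -0.09 (24.1) for oxidative phosphorylation, -0.0043 (38.4) for the basal squamous genes and 0.20 (91.8) for proteases, all in C666-1. In HK-1 they had 0.43 (94.0) for glycolysis, -0.10 (61.5) for interferon-stimulated genes and -0.43 (8.43) for NRF2 targets. Quantile normalization set 2 further lists apart in HK-1, keratinocyte terminal differentiation (1.14) and WNT and Notch (1.36), and 2 in C666-1, keratinocyte terminal differentiation (98.1) and proteases (97.51). With no filter on dim probes, EMT genes (1.32) and macrophage markers (99.0) stood apart in HK-1, and 4 lists stood lower in C666-1: basal squamous genes (0), keratinocyte differentiation (0.51), proteases (2.21) and WNT and Notch (0.03). Signal on all 4 arrays set apart NF-kB (98.2), EMT (2.06) and NRF2 targets (1.02) in HK-1, and EMT (0.25) and proteases (99.0) in C666-1. The mean of all probes set apart p53 targets (1.74) and BH3-only and effector genes (1.66) in C666-1.

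Few markers of other cell types were measured on both arrays of a line, apart from fibroblast markers in C666-1. Lymphocyte markers had -1.21 (3 genes, percentile 5.10) in HK-1 and -0.57 (3 genes, 4.87) in C666-1, with CD79A at -2.25 and -1.28, CD3D at -0.92 and -0.57, and PTPRC, measured in C666-1 only on the probe used, at 0.95. Another PTPRC probe was well above background on both HK-1 arrays and gave -0.42 there after 75th percentile scaling. Macrophage markers had 0.15 (3 genes, 87.9) in HK-1, and neural and neuroendocrine markers had 0.50 (3 genes, 84.7) and 0.12 (5 genes, 76.1). Fibroblast markers went both ways in C666-1 around a median of -0.02 (8 genes, 51.3): 3 lay above the median gene and 5 below, with THY1 at 0.96, FBLN1 at -0.04, LUM at -1.25 and DCN at -2.71. There the log2 signal over the 75th percentile was 2.63 and 3.71 for THY1 and 3.42 and 3.50 for FBLN1 in wild type and knockout. Under 3 genes were measured for fibroblast markers in HK-1 (median -1.94), for macrophage markers in C666-1 (-0.52) and for endothelial markers in both lines (-0.92 and -0.61).

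**Figure D2:**
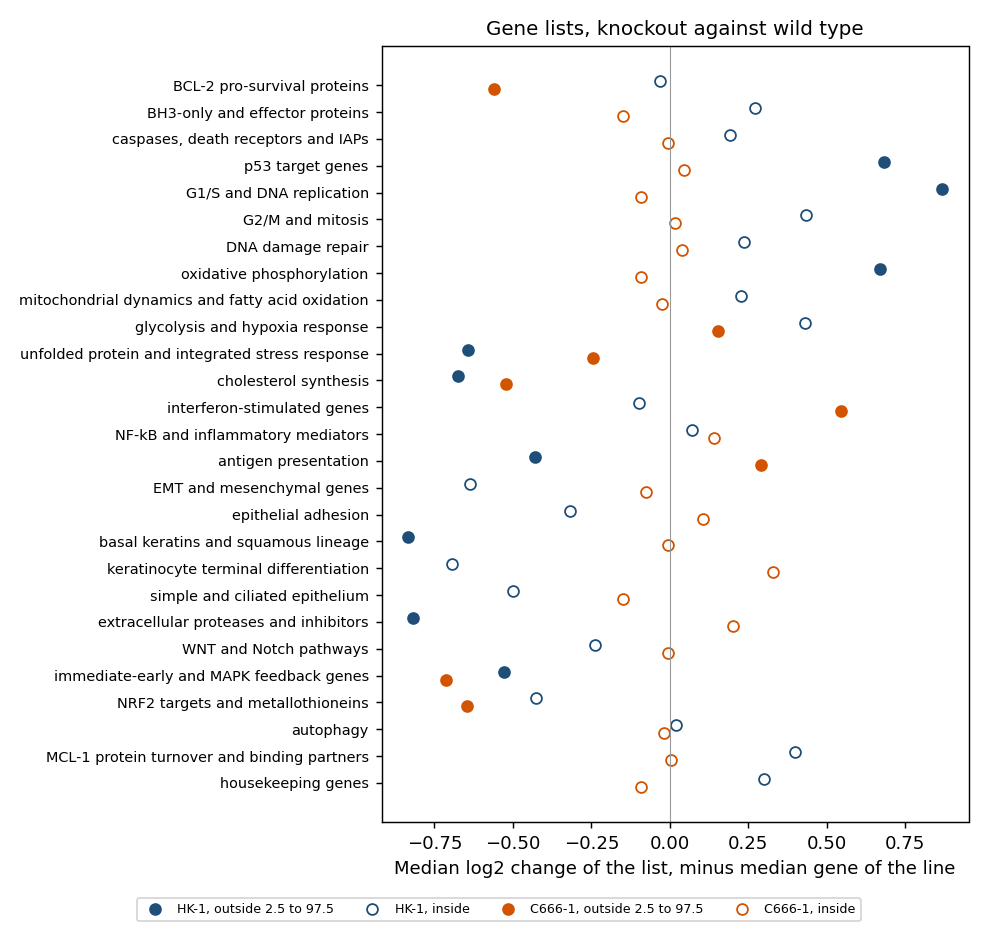
Median log2 change of each gene list, cell type markers aside, relative to the line's median gene (x axis, log2 units), with 1 point per list and line, HK-1 and C666-1, and filled points for lists apart from 10000 matched random lists. The G1/S list lay at 0.87 in HK-1 and -0.09 in C666-1, and cholesterol synthesis lay at -0.68 and -0.52.

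The changes of the lines were compared gene by gene to see what the knockouts had in common. The genes at least 2-fold lower in both included the immediate-early transcription factors EGR2 (-3.16 in HK-1 and -2.79 in C666-1) and FOS (-1.94 and -2.01). They also included many small nucleolar RNAs, which guide the chemical modification of ribosomal RNA, such as SNORD10 (-2.41 and -2.17), SNORA54 (-2.47 and -2.03), SNORA27 (-2.27 and -1.76), SNORD59B (-1.94 and -1.76), SNORA2A (-1.92 and -1.69), SNORD1C (-2.27 and -1.64) and SNORD61 (-1.87 and -1.65), and the protein-coding CIMAP1D (-1.88 and -1.74). Genes higher in both included the cell cycle kinase CDK6 (1.14 and 1.17), its antisense transcript CDK6-AS1 (1.07 and 1.45), the lipid kinase PIP4K2A (0.97 and 1.59), CCDC71 (1.21 and 1.02), TRMT2B (0.87 and 1.35), RDH10 (0.80 and 1.36), SLC25A43 (0.96 and 1.00), ZNF227 (0.75 and 1.08) and NUFIP1 (0.75 and 0.99). A second probe of TRMT2B gave -0.10 and -0.46 after 75th percentile scaling, and ZNF227 lay beside 2 bright spots on the C666-1 wild-type array.

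Of 11999 genes measured on all 4 arrays, 59 were at least 2-fold lower in both lines after 75th percentile scaling, against 19.3 for independent lists, and 36 of the 59 were small nucleolar or Cajal body RNAs. In the higher direction 18 genes were shared, against 36.0 for independent lists. Relative to the median gene, 120 were lower in both (48.9 for independent lists) and 3 higher (8.67). Across these genes, which are not independent replicates, the log2 changes of the lines did not correlate (Pearson r = 0.005, Spearman rho = 0.001). Opposite changes were found for 38 genes higher in HK-1 and lower in C666-1 (61.6 for independent lists) and for 33 the other way (11.3). Relative to the median gene these counts were 21 (29.5) and 40 (14.4). Genes lower in HK-1 thus exceeded the independent count both among genes lower and among genes higher in C666-1. The independent counts take no account of signal, so the excess of genes lower in both does not by itself show a shared direction.

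Small RNA classes were then set out by name, a choice made after the shared genes had been seen. The 222 small nucleolar and Cajal body RNAs measured on all 4 arrays had a median relative log2 change of -1.28 in HK-1 (216 of 222 below the median gene) and -0.84 in C666-1 (200 of 222 below), at percentile 0 of matched random lists in both lines. The 55 replication-dependent histone genes, whose mRNAs end in a stem-loop and lack a poly(A) tail, had a median of 0.16 in HK-1 (percentile 15.6) and of -0.996 in C666-1, where 55 of 55 lay below the median gene (percentile 0). The 17 SNHG transcripts, which host small nucleolar RNAs in their introns, had medians of -0.21 (percentile 1.5) and -0.22 (percentile 0.735). The sign of the small nucleolar RNA medians was the same after quantile normalization. Against genes of the same mean signal over the 4 arrays, they lay at -1.14 in HK-1 and -0.77 in C666-1.

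**Figure D3:**
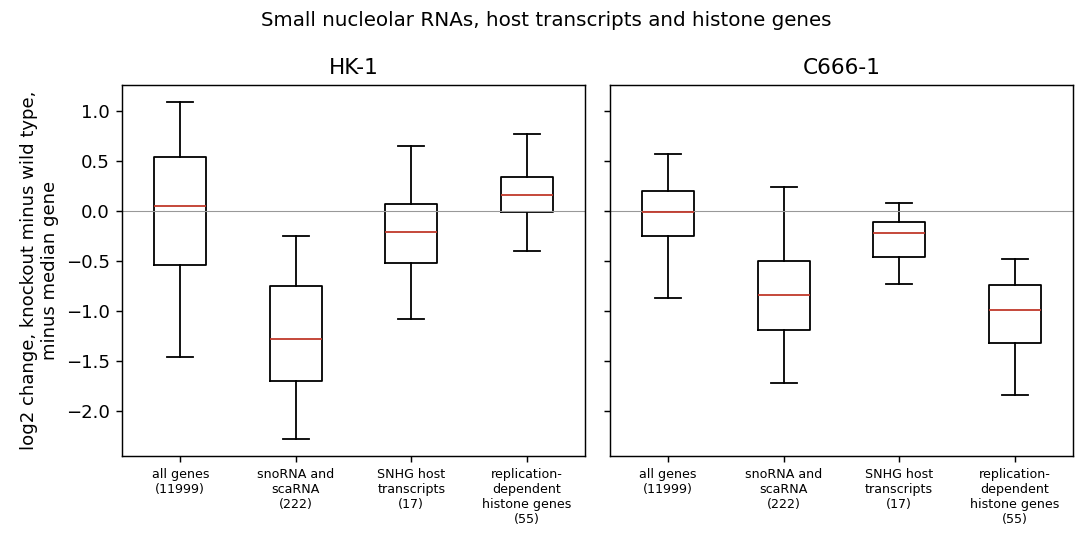
Log2 change relative to the line's median gene (y axis, log2 units) of small nucleolar and Cajal body RNAs (222), replication-dependent histone genes (55) and SNHG host transcripts (17), beside all 11999 genes, in HK-1 and C666-1. Boxes are quartiles, whiskers span the 5th to 95th percentiles of genes and red lines are medians, which lay at -1.28 and -0.84 for the small nucleolar RNAs.

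**Figure D4:**
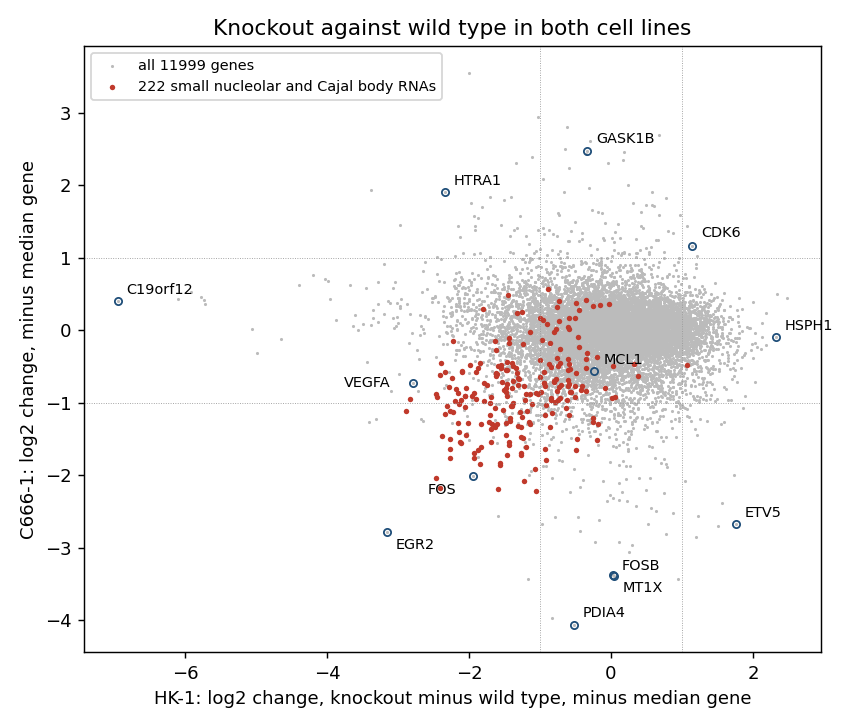
Log2 change relative to the line's median gene in HK-1 (x axis) and C666-1 (y axis), in log2 units, for the 11999 genes measured on all 4 arrays, with 1 point per gene, red for small nucleolar and Cajal body RNAs and circles for genes labelled by symbol. Small nucleolar RNAs lay mostly where both lines were lower, and the cloud was wider along the HK-1 axis.

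In the fit over both lines, limma called 32 of 15093 genes at a Benjamini-Hochberg adjusted p under 0.05, of which 6 rose and 26 fell. The p-values belong to the 75th percentile scale, and the changes are given relative to the median gene. EGR2 fell in both lines, with a mean relative log2 change of -2.97 (SE 0.53, limma adjusted p = 0.000354). SNORD10 (-2.29, SE 0.48, adjusted p = 0.0131) and SNORA54 (-2.25, SE 0.48, adjusted p = 0.0186) fell likewise. EGR3, a relative of EGR2, was well above background in both wild types and in neither knockout, at least 2.35-fold lower in HK-1 and at least 6.21-fold lower in C666-1 (limma adjusted p = 0.000805). SMCR5 was at least 1.99-fold and 6.11-fold lower (0.0155). SEMA5A was at least 5.25-fold lower in HK-1 and had -4.44 in C666-1 (3.85e-05). SLC8A1-AS1, the antisense transcript of a sodium-calcium exchanger gene, was at least 1.94-fold higher in HK-1 and 2.24-fold in C666-1 (0.00251), and its C666-1 knockout spot lay beside a bright one. These p-values were computed from the genes' own values, including those not well above background, and do not belong to the bounds. With such values raised to the array's lowest well-above-background signal, limma's adjusted p was 0.116 for EGR3, 0.228 for SMCR5, 0.926 for SLC8A1-AS1 and 4.28e-06 for SEMA5A, and 20 of the 32 calls were kept.

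Several calls of the fit rested on 1 line. C19orf12 (adjusted p = 6.63e-07 by limma), GPR179 (0.00161) and NUDT11, at least 12.1-fold lower (0.000353, and 0.146 with dim values so raised), were low in the HK-1 knockout alone, with C666-1 changes of 0.40, 0.04 and -0.40. NR3C1 (1.77e-09) and SMPX (0.00696) were low in the C666-1 knockout, where NR3C1 had -0.19 in HK-1 and SMPX was not well above background there. Of the 32 calls, 20 rested on 1 line, 12 had values at least 2-fold the same way in both, those not well above background included, and 4 of these 12 were measured on all 4 arrays: EGR2, SNORD10, SNORA54 and the ribosomal RNA gene RNA18SN5, which the naming rule did not cover and which was named after its values were seen. SNORD10, SNORA54 and RNA18SN5 are RNAs without a poly(A) tail, for which poorer copying stays open. At an unadjusted p under 0.05 there were 733 genes, against 755 for no change at all. The count of calls fell to 0 with quantile normalization and to 0 without the cell line in the fit.

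No list was called by limma's fry over both lines: the smallest p was 0.0518, for the unfolded protein and integrated stress response, at an adjusted p of 0.620. At an unadjusted p under 0.05 there were 0 lists with fry and 0 with camera at an estimated correlation, over the 31 lists of at least 3 genes. With median scaling, fry called 3 lists. Adjusted over the list alone, limma called 5 immediate-early genes (EGR1, EGR2, EGR3, FOS and FOSB) against 2 over all genes, and EGR1 had a mean relative change of -1.54 (SE 0.48) and FOS of -1.98 (SE 0.47). EGR2 and FOS were at least 2-fold lower in both lines, but FOSB had 0.02 in HK-1 and -3.38 in C666-1. Adjusted over the list alone, MT1X, MT2A and OSGIN1 were called among the NRF2 targets and metallothioneins, HES1 and JAG1 among WNT and Notch genes, and 1 gene each in 7 other lists: PDIA4, VEGFA, TGFBI, ELF3, DSC2, ADAMTS1 and CD79A. Such calls could rest mainly on 1 line: MT1X had 0.04 in HK-1 and -3.39 in C666-1, and PDIA4 had -0.53 and -4.06. CD79A was at least 2-fold lower in both lines. With dim values raised as above, OSGIN1, HES1, JAG1, TGFBI, ELF3, DSC2 and ADAMTS1 were no longer called, and SPRR3, of keratinocyte differentiation, and DCN, of the fibroblast markers, were. Over all genes, PDIA4 was the only one of these that was also called, and the remaining 22 of the 32 lists had 0 calls either way before dim values were raised.

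The lines themselves differed far more than knockout and wild type did. C666-1 wild type had more transcript of the fibrillar collagen COL5A2 (10.23 log2 units above HK-1), the transcription regulators ID2 (8.07) and NR2F1 (7.90), WTIP (7.58), A1BG (7.32) and MARCKSL1 (7.30). HK-1 wild type had more of the basal keratin KRT15 (-12.44, C666-1 minus HK-1), the squamous calcium-binding S100A2 (-11.35), the stress cytokine GDF15 (-11.23), the matrix proteins TGFBI (-10.53), EFEMP1 (-10.36) and IGFBP7 (-10.12), the epithelial 14-3-3 protein SFN (-9.95) and tissue factor F3 (-9.63). COL17A1 (-8.18) and NGFR (-6.49), from the squamous list, and EPCAM (-6.87), from the adhesion list, were also higher in HK-1. Over both genotypes, limma called 6908 of 15093 genes (45.8%) at adjusted p under 0.05, of which 4293 were higher and 2615 lower in C666-1.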

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

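The differences given here were chosen by size after the fold changes were seen, and none of them was tested, since each line had 1 array per group. They were picked out because the change ran one way on the arrays of one line and the other way on those of the other, by at least 2-fold after 75th percentile scaling for the genes, and outside matched random lists for the gene list.

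ADGRL3, a latrophilin adhesion receptor, had a relative log2 change of -2.0 in HK-1 and 3.55 in C666-1, so C666-1 minus HK-1 was 5.55. Its second probe was not well above background on both arrays of either line, so these values rest on 1 probe. ETV5, a transcription factor induced by MAPK signalling, had 1.76 and -2.68, a difference of -4.43. The small GTPase gene RAP2A had 1.50 and -2.70, a difference of -4.20, and HTRA1, a secreted serine protease, had -2.34 and 1.91, a difference of 4.25. DPYD, which degrades pyrimidines, had 1.56 and -2.38, a difference of -3.94, but its second probe gave 0.08 in HK-1 after 75th percentile scaling, so its HK-1 value rests on 1 probe. TOMM40, the channel of mitochondrial protein import, had 1.74 and -2.0, a difference of -3.74.

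The antigen presentation list stood apart in both lines in opposite directions, with a relative median of -0.43 in HK-1 and 0.29 in C666-1, a difference of 0.72.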

How the results depend on the processing

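Robust moderation, changes relative to the median gene, keeping blemished spots, using spot flags only and raising dim values to a floor were chosen after the data had been seen, and the other alternatives before. Of 158 counts compared, 116 stayed within 1.5 times the value reported and 42 moved further. Median scaling, changes relative to the median gene and the authors' table leave each list's relative median as it was, to within 0.001, so 7 of the 10 alternatives run on the lists could move it. Under these 7, of 420 list medians 13 moved by more than the SD between probes, and of 707 values of named genes 79 moved and, among values called 2-fold, 1 changed sign. Sign changes of values not called 2-fold are not in this count, such as that of MCL1 in HK-1, at 0.23 with no filter on dim probes. The reported counts were 3391 genes 2-fold in HK-1, 746 in C666-1 and 77 in both lines, 32 called by limma over both lines, 6908 between the lines, and 0 lists called by fry. In HK-1 9 lists stood apart and in C666-1 8, and of these 17 calls 12 held under all 7. A further 17 calls, of 13 combinations of list and line, appeared under 1 or more of the alternatives.

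Normexp gave 350 lower genes in HK-1, 323 in C666-1 (157 higher, 166 lower), 30 in both lines (18 lower) and 13 called by limma, and ZNF227 turned to -0.33 in HK-1, cause not tested. Quantile normalization gave 1344 higher genes in HK-1 and 0 called by limma. Scaling to the median gave 1443 higher genes in HK-1, 9 higher in both lines and 3 lists called by fry. The last 2 scalings lowered the HK-1 median change from 0.35 to 0.14 and 0.15, and why the calls of limma and fry moved was not tested. With changes relative to the median gene, HK-1 had 862 higher and 1733 lower genes, both lines shared 123 (3 higher, 120 lower) and limma called 67, which follows from moving the zero point.

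With no filter on dim probes, HK-1 had 5104 genes (2174 lower), C666-1 2254 (1014 higher, 1240 lower), both lines 274 (76 higher, 198 lower) and limma called 138, as more genes near background entered. Requiring signal on all 4 arrays left 496 genes in C666-1 (183 higher), 18 called by limma and 4437 between the lines, as fewer genes were counted. A 1.5-fold rule gave 6987 genes in HK-1 (5058 higher, 1929 lower), 2482 in C666-1 (1372 higher, 1110 lower) and 442 in both lines (220 higher, 222 lower), by its construction. Without the cell line in the fit limma called 0 genes, since the difference between lines then entered the spread. Robust moderation gave 17, cause not tested. With values not well above background raised to the array's lowest well-above-background signal, limma called 22 genes, 20 of them among the 32. The authors' table, the mean of all probes, keeping blemished spots, using spot flags only and eBayes without trend moved no count beyond 1.5 times, and camera called 0 lists. Leaving out 1 cell line leaves no residual degrees of freedom, so the value is then the other line's fold change, with no test.

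Knockout and wild type were paired within each cell line through the term for the line in the fit. Replicate numbers add no pairing, as each group holds 1 array. Signal over background limits which genes were counted, since 45.8 to 50.1% of the gene spots on an array were well above it.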

Other observations

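Among the tests reported in this part, those of array scaling and signal strength, of the HK-1 wild-type array, of single probes, of host genes, of 1 shared RNA, of blemishes and of the C666-1 histone genes were chosen after the result had been seen. The tests of histone genes over both lines and of SNHG host transcripts were written before, although how their values were judged was changed to the more cautious reading afterwards.

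The lower signal of the small nucleolar RNAs ran through each of their classes. The 111 C/D box RNAs, which guide ribose methylation, had a median relative log2 change of -1.32 in HK-1 (109 below the median gene) and -0.84 in C666-1 (99 below). The 91 H/ACA RNAs, which guide pseudouridine formation, had -1.23 (87 below) and -0.82 (82 below), and the 20 Cajal body RNAs had -1.43 (20 below) and -0.90 (19 below). Across the 222 RNAs, which are not independent replicates, the changes of the lines correlated at 0.336, against 0.005 across all genes. Replication-dependent histone genes moved apart from the G1/S genes in both lines: they lay at -0.71 relative to the G1/S median in HK-1 and at -0.90 in C666-1.

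For the small nucleolar RNAs, signal strength was argued against as the cause of the drop relative to other genes. After quantile normalization these RNAs still lay at -0.77 in C666-1 and -1.14 in HK-1 relative to genes of the same signal. That test cannot decide the choice of scale, since quantile normalization also takes its zero from the bulk of genes. After 75th percentile scaling the spike-ins lay at -0.56 in HK-1 and -0.48 in C666-1, and the median gene at 0.35 and 0.12. The spike-ins thus also lay below the median gene, so the size of the drop depends on the reference. Poorer copying of RNA without a poly(A) tail is a candidate explanation in C666-1, where histone genes lay at -0.996, and it stays open over both lines: in HK-1 they lay at 0.16, but G1/S genes lay at 0.87 there, so histone genes were no fixed reference and a bound of -0.25 on them alone was the wrong one. Ribosomal RNA also lacks a poly(A) tail, and its gene RNA28SN5 lay at -0.83 in HK-1 and -3.97 in C666-1. Lower transcript levels of host genes were argued against as the whole cause: the 122 measured genes whose span holds 196 of these RNAs, strand aside, lay at 0.24 in HK-1 and -0.09 in C666-1, at least 0.759 above the RNAs, and the quartile ranges did not overlap. Transcription itself was not measured. A part of the drop stays open, as SNHG transcripts lay at -0.21 in the line nearer to 0, above the bound of -0.25 by less than their spread (lower quartile -0.52 in HK-1). A knockout effect on these RNAs may remain as a hypothesis, untested here, since each knockout had 1 sample.

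The changes in HK-1 were spread more widely than in C666-1. Their median absolute deviation, scaled to stand for the SD of a normal spread, was 0.82 against 0.35. Error of single probes was argued against as the whole cause, because the changes of 2 probes of a gene correlated at 0.638 across 3420 HK-1 genes; a first form of that test, the SD between probes of 0.49 against the spread of 0.82, had met neither of its bounds. An HK-1 wild-type array that stands apart is consistent with the data: it correlated at 0.798 and 0.782 with the C666-1 arrays, against 0.837 and 0.820 for the HK-1 knockout array, and the median change climbed from -0.22 in the dimmest of 5 signal classes of genes to 0.69 in the brightest, a gap of 0.913. The correlations alone cannot say which array departed. By them, the C666-1 knockout array also lay further from both HK-1 arrays than the C666-1 wild-type array did. Whether the HK-1 wild-type array, its RNA or the knockout set the spread stays open with 1 array per group.

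On the HK-1 knockout array, 104 probes were over 16-fold dimmer than on the wild-type array, 46 of them with a gene name, among them C19orf12 and NCR1. A single RNA binding all of these probes could not be excluded: the 34 measured in C666-1 had a median log2 change of 0.41 (27 higher) and an SD of 0.38, which is 0.704 of that of random probes of the same signal, and 1.9% of random sets had an SD as small. Blemishes on the HK-1 wild-type array stay open as well, as does the knockout itself, which was not tested, and the outcome changed with the form of the test. With 31 of 104 probes (29.8%) within 6 rows and 1 column of another, against 6.02% of random probes, the share lay between the bounds; within 10 rows and 10 columns it was 51.0% against 49.2%, and 21.2% of the probes had at least 20% bright neighbours, against 3.32% of all probes. On the HK-1 wild-type array 141 spots outside blemishes were over 16-fold brighter than on the line's other array, against 15, 77 and 19 on the HK-1 knockout, C666-1 wild-type and C666-1 knockout arrays, so a value resting on 1 probe may be such a spot.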
